A study of Mus musculus with 6 samples.

How the data were processed

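The series measured gene expression by RNA sequencing in 6 mouse libraries. The mice, of the C57BL/6 strain, carried a Cre recombinase under the Tie2 promoter, which is active in endothelial cells and in part of the blood cell lineage, together with a tdTomato reporter that Cre switches on. Myocardial infarction (MI) was induced by tying off the left anterior descending coronary artery, and tissue was taken 3 weeks later, per the labels' protocols. Infarct tissue or normal left ventricle was dissociated with collagenase, and cells positive for tdTomato and negative for the macrophage antigen F4/80 were sorted. RNA was copied to cDNA and amplified by T7 in vitro transcription before library preparation and paired-end sequencing, per the labels' protocols. Amplification of this kind can widen the spread between libraries made from little RNA.

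The 6 libraries fell into 2 groups of 3, called MI and Normal here, from the tissue labels. The titles give each group the same numbers, Ms1535, Ms1537 and Ms1608. The labels of the Normal samples state that no infarct surgery was done, so whether samples with the same number came from the same mouse was left open. Nothing in the labels describes how the 3 samples of a group differ apart from their number, so p-values measure the spread between these libraries.

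The deposited table holds FPKM values (fragments scaled by transcript length and by the mapped total of the library) for 45038 genes, with 1 column per library. The submitters' processing notes name STAR 2.4.2a, an aligner, and Cufflinks 2.2.1, which estimates transcript abundance, together with the mouse genome build GRCm38. The gene annotation release, the strand setting and the treatment of multi-mapping reads were not given in the sources used here. Of the gene identifiers, 44394 (98.6%) were found in the GENCODE annotation used here for positions on GRCm38. In the table, 27 gene symbols had been turned into dates by spreadsheet software and 119 symbols occurred more than once, so genes were followed by identifier.

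FPKM values are not counts, and each library's depth was read from its low values, which fall on steps of 1 fragment once multiplied by the length of the gene. Between 82.3% and 87.3% of the low values tested lay within 0.1 of a whole number, where evenly spread values would give 20%. The step was fitted to these same values, so this share is not an independent check. The implied totals were 46.2, 39.2 and 33.1 M fragments (M for the prefix mega) in MI Ms1535, Ms1537 and Ms1608 and 41.2, 33.2 and 35.8 M in Normal Ms1535, Ms1537 and Ms1608. On a gene of 2 kb, 3 fragments then correspond to 0.0324 to 0.0453 FPKM, depending on the library, which covers counting error only. The labels' protocol states about 10 M reads per sample, and the difference from these totals was not reconciled. A common error in the step would leave the ratios of totals between libraries as they are, but not the totals or the FPKM of 3 fragments. Each library listed between 21924 and 23850 genes at 0. Several mitochondrial genes that cells need were among them, so a 0 can be a failed estimate and is given here only as listed at 0.

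Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested, which left 10168. MI was compared with Normal by limma (version 3.58.1 in R 4.3.3) with a mean-variance trend on log2(FPKM + 1), with the group as the only term and with the deposited values not scaled further. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. A log2 difference is MI minus Normal on the log2(FPKM + 1) scale, which understates changes of genes with low values. With 3 libraries against 3, the smallest p that an exact two-sided permutation test could give is 0.1, so no such test was used for single genes.

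Gene lists for 38 cell types, pathways and complexes were written from textbook knowledge. They hold 727 genes, of which 721 were in the table, and 35 lists had the minimum of 5 tested genes. Each was tested with limma's camera, which asks whether the genes of a list stand higher or lower than all other tested genes, at a preset correlation between genes of 0.01, with adjustment over the 35 lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance one way, were run beside it. For each list, members past the threshold were counted over all tested genes and again adjusted over the list alone.

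Genes named in the text follow a rule. It takes the 10 genes with the largest change in each direction past the threshold with no overlap between groups, filled by lowest unadjusted p where fewer passed, leaving out predicted genes, small RNAs and pseudogenes. It also takes up to 3 members of each list, and a fixed set: Tek, Pecam1, Cdh5, Vwf, Adgre1, Ptprc, Pdgfrb, Pdgfra, Met, Snai1, Fap, Cdh2, Acta2, Col1a1, Postn and Fn1. The test, the filter, the lists, this rule and most of the other settings tried were chosen before the data were examined. These settings were other pseudocounts (0.1, 0.5 and 5), other filters, 3 scalings (median ratio, upper quartile and quantile), a replicate block, limma without the trend or with robust estimation, library weights, each library left out in turn, and other thresholds. Libraries left out in turn kept the same 10168 genes. Leaving out both Ms1608 libraries, and leaving out 1 or both together with scaling or a block, was added after seeing the data. Genes named outside the rule, which are Gm24890, Gpihbp1, Car4 and those in the closing section, and the genes taken from comparisons without a Ms1608 library were chosen after their values were seen.

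The gene test was tested on simulated data made from the real values, with 50 genes changed at each of 4 sizes. Changed genes were taken from those with a mean log2(FPKM + 1) above 2. The simulated noise was independent between genes and libraries, so an outlying library such as Normal Ms1608 was not reproduced. With all 6 libraries, 0% of genes with a true log2 difference of 1, 4% of those at 2, 46% at 4 and 72% at 6 were recovered, with 4 false calls among 10168 genes. Without Normal Ms1608, the shares were 0%, 6%, 70% and 80%, with 7 false calls. Changes of 2 log2 units or less were thus rarely detectable with these libraries. Near-identical genes, such as immunoglobulin, H2, globin, Ear, Pilrb and Ly6c genes and copies of small nuclear RNAs, may share fragments, so their values are uncertain.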

Results

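RNA was sequenced from cells of the Tie2-Cre lineage, positive for tdTomato and negative for F4/80, sorted from mouse infarct tissue 3 weeks after surgery or from normal left ventricle. There were 3 MI and 3 Normal libraries, with implied depths of 33.1 to 46.2 M (mega) fragments read from the low values, whereas the labels' protocol states about 10 M reads per sample, which was not reconciled. The series concerns cardiac endothelial cells in infarcted tissue, and the comparison asked how their expression differs from that of the same sorted population in normal muscle. Among 5 of the libraries, correlations of log2(FPKM + 1) across genes lay between 0.80 and 0.92, whereas Normal Ms1608 correlated with them at 0.54 to 0.68. Genes are not independent replicates, so these values only describe the libraries. Normal Ms1608 held 0.486 FPKM of Kdr, the main endothelial VEGF receptor, against 73.9 and 44.6 in Normal Ms1535 and Ms1537. It held 174 FPKM of Ptprc, the leukocyte antigen CD45, against 3.13 and 4.72.

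Genes of the interstitial matrix, which encode collagens and other parts of connective tissue, were called higher as a group in MI relative to all other genes by limma's camera at a preset correlation, with a median log2 difference of 2.58 over 35 genes (adjusted p = 3.55e-09, and adjusted p = 0.816 with an estimated correlation, where the call was lost). Fibroblast markers (median 2.398, 17 genes) and genes of mesenchymal transition (median 1.80, 18 genes) were called higher as well, and both calls were lost with an estimated correlation (adjusted p = 0.816 for each). Markers shared by leukocytes (median 1.80, 18 genes) and T and NK cell markers (median 1.72, 17 genes) were also called higher than other genes, but not with an estimated correlation (adjusted p = 0.863 and 0.816). Pan-endothelial genes (median 0.38, 29 genes) and genes of cardiac capillary endothelium (median 0.30, 22 genes) were called lower than other genes, but not with an estimated correlation (adjusted p = 0.816 for both). The capillary call was also lost after quantile scaling (adjusted p = 0.0815). In these 7 lists 0 members passed the limma threshold over all genes. The median tested gene itself lay 0.78 log2 units higher in MI, so these list calls are relative to that shift, which was 0.27 after median-ratio, 0.20 after upper-quartile and -0.05 after quantile scaling.

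The interstitial matrix list stood 1.80 above the median of all genes, and 34 of its 35 members had values above 0 (limma camera, adjusted p = 3.55e-09, and adjusted p = 0.816 with an estimated correlation). By limma, 0 of its members passed the limma threshold over all genes, while 26 had an unadjusted p under 0.05 and 24 passed adjusted over the list alone. Postn, a matrix protein of scar-forming fibroblasts, was measured at 309.7, 705 and 41.7 FPKM in MI Ms1535, Ms1537 and Ms1608 and at 14.3, 14.8 and 2.07 FPKM in the Normal libraries. Its log2 difference was 4.54 (SE 1.08, limma adjusted p = 0.245). Col1a1, a chain of type I collagen, had 112 ± 116 FPKM in MI and 8.06 ± 4.42 FPKM in Normal (SD, n = 3 each), a log2 difference of 3.16 (SE 0.94, limma adjusted p = 0.245). Col3a1, which encodes type III collagen, had 774, 762 and 42.7 FPKM in MI against 22.6, 21.2 and 40.9 FPKM. Fn1, the gene for fibronectin, had 277, 95.7 and 19.6 FPKM against 6.13, 5.49 and 122.7 FPKM, so that Normal Ms1608 lay above MI Ms1537. The list median was lowest among MI libraries in MI Ms1608, at 3.03 log2(FPKM + 1), and was 0.79 in Normal Ms1608 against 2.22 and 2.54 in Normal Ms1535 and Ms1537.

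Fibroblast markers gave a camera adjusted p of 2.05e-05, and an adjusted p = 0.816 with an estimated correlation, with 0 members past the limma threshold over all genes, 11 at an unadjusted p under 0.05 and 10 of 17 adjusted over the list alone. Of these 17 genes, 12 also stand in another list. The list was not called without Normal Ms1608 (camera adjusted p = 0.128, the highest over 23 settings, against 4.19e-09 as the lowest). In Normal Ms1608 its median was 1.15 log2(FPKM + 1), against 3.93 and 3.99 in the other Normal libraries. Dcn, the gene of the collagen-binding proteoglycan decorin, had 2151 ± 1265 FPKM in MI and 447 ± 310 FPKM in Normal (SD, n = 3), a log2 difference of 2.398 (SE 0.84, limma adjusted p = 0.252). Pdgfra, a growth factor receptor used as a fibroblast marker, was at 7.40 ± 6.07 FPKM in MI and 0.849 ± 0.712 FPKM in Normal (log2 difference 2.01, SE 0.70, limma adjusted p = 0.252). Fap, a protease of activated fibroblasts, was at 1.77, 6.28 and 1.33 FPKM against 1.39 and 0.478 FPKM, and was listed at 0 in Normal Ms1608.

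Genes of mesenchymal transition gave a camera adjusted p of 0.000925 (adjusted p = 0.816 with an estimated correlation), with 0 of 18 members past the limma threshold, 7 at an unadjusted p under 0.05 and 6 adjusted over the list alone. S100a4, a calcium-binding protein, had 1616 ± 1223 FPKM in MI and 505 ± 369 FPKM in Normal (log2 difference 1.80, SE 0.90, limma adjusted p = 0.332). Snai1, a transcription factor that represses Cdh5, had 3.70 ± 2.07 FPKM against 0.985 ± 0.843 FPKM (log2 difference 1.26, SE 0.57, limma adjusted p = 0.305). Acta2, smooth muscle actin, had 7.45 ± 5.72 FPKM against 1.42 ± 1.74 FPKM (log2 difference 1.79, SE 0.77, limma adjusted p = 0.298). Pdgfrb, Met and Cdh2 lay below the expression filter and were not tested. Pdgfrb, the receptor for PDGF-B, had 4.10, 10.6 and 0.975 FPKM in MI and 0.854, 0.361 and 0.0407 FPKM in Normal. Met, the hepatocyte growth factor receptor, had 5.52, 1.66 and 0.330 FPKM against 0.0968, 0.0216 and 0.0868 FPKM. Cdh2, N-cadherin, had 4.17, 0.469 and 0.488 FPKM against 0.294, 0.113 and 0.0681 FPKM.

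Leukocyte markers were high in all MI libraries and in Normal Ms1608. The pan-leukocyte list had medians of 5.65, 5.70 and 5.89 log2(FPKM + 1) in MI Ms1535, Ms1537 and Ms1608, of 2.46 and 2.88 in Normal Ms1535 and Ms1537, and of 6.45 in Normal Ms1608. With all 6 libraries its camera adjusted p was 0.0273 (adjusted p = 0.863 with an estimated correlation), with 0 of 18 members past the limma threshold, 4 at an unadjusted p under 0.05 and 1 adjusted over the list alone. T and NK cell markers gave the same adjusted p of 0.0273 (adjusted p = 0.816 with an estimated correlation), with 0 of 17 past the limma threshold, 6 at an unadjusted p under 0.05 and 0 adjusted over the list alone. Neither list was called without Normal Ms1535 (camera adjusted p = 0.804 for both), without Normal Ms1537 (0.481 and 0.117) or without MI Ms1608 (0.434 and 0.0854), and the T and NK list not without MI Ms1537 (0.110). Pseudocounts of 0.1 (camera adjusted p = 0.0599 and 0.05795) and 5 (0.108 and 0.0838) ended both calls. A mean of at least 5 FPKM as the filter ended that of T and NK markers (0.0606). Both lists stayed called after median-ratio scaling (camera adjusted p = 0.000822 for pan-leukocyte and 0.00206 for T and NK markers). They were called higher in 18 and 16 of 23 settings, with adjusted p up to 0.804 for both. Ptprc was at 74.1 ± 4.85 FPKM in MI and 60.5 ± 98.1 FPKM in Normal (SD, n = 3), a log2 difference of 2.23 (SE 1.25, limma adjusted p = 0.376). Cd52, a surface glycoprotein of lymphocytes, had 1548 ± 268 FPKM against 1122 ± 1477 FPKM (log2 difference 1.39, SE 0.87, limma adjusted p = 0.417). Adgre1, which encodes the F4/80 antigen that the sort excluded, was below the filter, at 0.282, 1.70 and 7.21 FPKM in MI and 0.128, 0.247 and 0.00904 FPKM in Normal. Macrophage and monocyte markers (median 1.45, camera adjusted p = 0.0665) and neutrophil markers (median 1.57, adjusted p = 0.0672) missed the threshold, each with an adjusted p = 0.816 with an estimated correlation. Both were called higher after median-ratio (camera adjusted p = 0.0213 and 0.0231), upper-quartile (0.0213 and 0.0223) and quantile scaling (0.00477 and 0.00118), and in 13 and 12 of 23 settings, with adjusted p up to 0.840 and 0.499.

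Endothelial lists were called lower than other genes, although their medians as deposited were above 0. Pan-endothelial genes lay -0.41 relative to the median of all genes (limma camera, adjusted p = 0.000925, and adjusted p = 0.816 with an estimated correlation), and their median turned from 0.38 to -0.26, -0.31 and -0.77 after median-ratio, upper-quartile and quantile scaling. Cardiac capillary genes lay -0.49 relative to it (adjusted p = 0.000925, and adjusted p = 0.816 with an estimated correlation), and their median turned from 0.30 to -0.43, -0.49 and -0.57. In both lists 0 members passed the limma threshold, 0 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone. Neither list was called without Normal Ms1535 (camera adjusted p = 0.804 for both) or without Normal Ms1537 (0.392 and 0.547). Without the filter on low values neither was called (camera adjusted p = 0.394 and 0.363), and their medians stood 0.299 and 0.256 above that of all genes. Quantile scaling ended the capillary call (adjusted p = 0.0815). Without Normal Ms1608 both deposited medians turned negative, to -0.66 for pan-endothelial (camera adjusted p = 6.71e-19, and adjusted p = 0.373 with an estimated correlation) and -0.98 for capillary genes (1.00e-24, and adjusted p = 0.301 with an estimated correlation). In that comparison Tek and Cdh5 had log2 differences of -0.35 and -0.34 (limma adjusted p = 0.701 and 0.781). The pan-endothelial median was 0.33 log2(FPKM + 1) in Normal Ms1608 against 4.21 and 3.74 in Normal Ms1535 and Ms1537 and 3.21, 4.53 and 2.52 in MI. Tek, the receptor Tie2 whose promoter drives the Cre, had 6.24 ± 5.26 FPKM in MI and 4.68 ± 4.08 FPKM in Normal (log2 difference 0.53, SE 0.91, limma adjusted p = 0.790), a difference that turned negative under all 3 scalings. Cdh5, VE-cadherin, had 37.6 ± 37.2 FPKM against 22.0 ± 19.7 FPKM (log2 difference 0.96, SE 1.21, limma adjusted p = 0.702), and its difference turned to -0.10 after quantile scaling. Pecam1, the adhesion protein CD31 that leukocytes also carry, had 14.7 ± 8.33 FPKM against 20.3 ± 7.63 FPKM (log2 difference -0.51, SE 0.71, limma adjusted p = 0.731). Vwf, von Willebrand factor, had 6.18 ± 5.75 FPKM against 3.25 ± 3.27 FPKM (log2 difference 0.81, SE 0.84, limma adjusted p = 0.634), and also turned negative after quantile scaling. Gpihbp1, which anchors lipoprotein lipase on capillaries, had 79.4, 176 and 58.6 FPKM in MI against 608 and 355 FPKM in Normal Ms1535 and Ms1537 and 3.32 FPKM in Normal Ms1608. Car4, a carbonic anhydrase of capillaries, had 8.31, 9.48 and 4.34 FPKM in MI against 42.6, 27.2 and 0.398 FPKM.

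**Figure D1:**
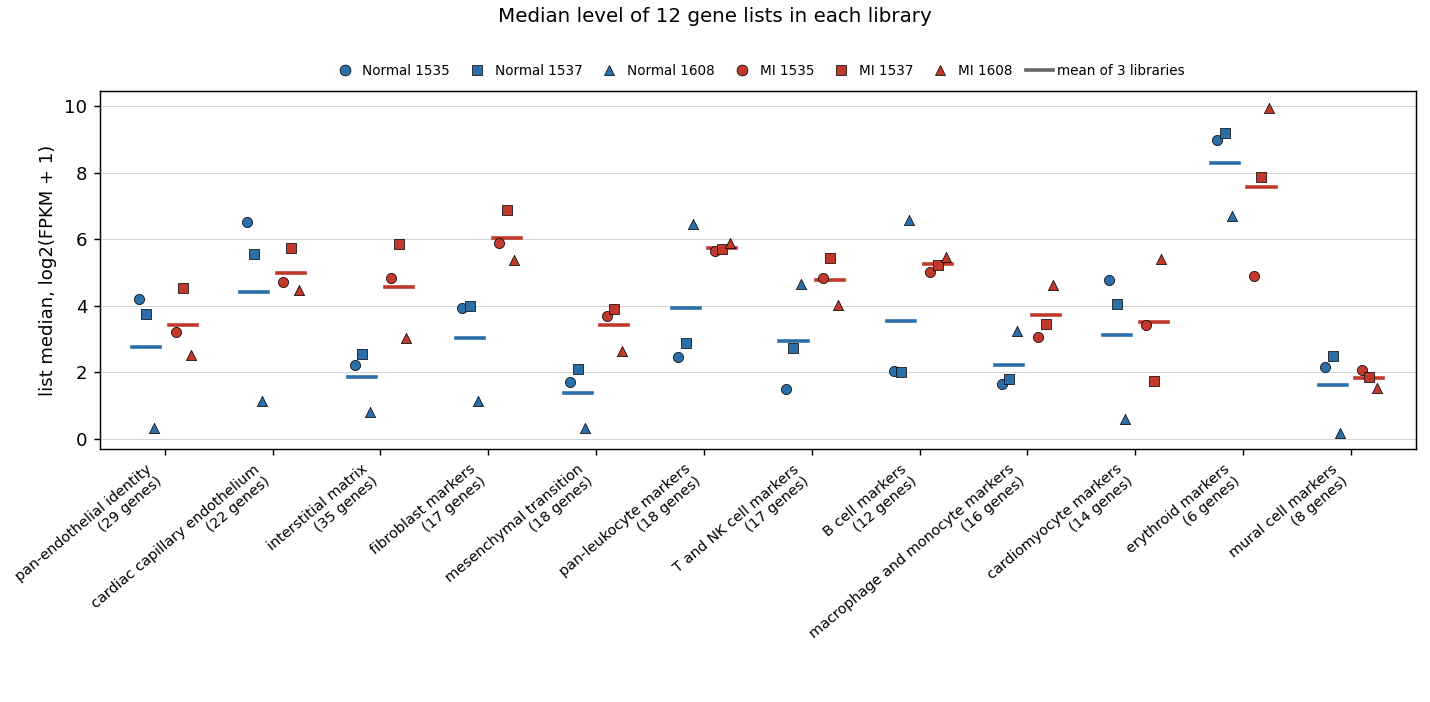
Median of log2(FPKM + 1) over the tested genes of 12 gene lists in each library, with Normal libraries in blue, MI libraries in red, symbols for the number in the sample title and bars for the mean of 3 libraries. In Normal Ms1608 the pan-endothelial median was 0.33 and the pan-leukocyte median 6.45. The interstitial matrix medians of the MI libraries, from 3.03 to 5.86, stood against 0.79 to 2.54 in the Normal libraries on the deposited scale. The list difference stayed above 0 under each scaling. Median-ratio scaling divides values by 0.995 in MI Ms1608 and by 0.572 in Normal Ms1537, so the medians of single libraries need not stay apart after it.

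A further 5 lists were called lower than other genes in MI. Nuclear-encoded genes of the respiratory chain had a median of 0.37 (camera adjusted p = 0.0154), interferon response genes 0.27 (adjusted p = 0.0254) and cardiomyocyte markers 0.23 (adjusted p = 0.0154), and all 3 medians turned negative under each scaling. Mitochondrially encoded genes had a median of -0.46 and a mean of -0.09 (adjusted p = 0.000925), and erythroid markers a median of -0.69 (adjusted p = 0.0110). For each of these 5 lists the call was lost, with an adjusted p = 0.816 with an estimated correlation, and 0 members passed the limma threshold over all genes or adjusted over the list alone, with 0 genes of the 5 lists lower at an unadjusted p under 0.05 and 2 interferon response genes higher, against the direction of that call. Median-ratio and upper-quartile scaling ended the calls of cardiomyocyte (camera adjusted p = 0.115 and 0.185), erythroid (0.124 and 0.160) and mitochondrially encoded genes (0.0612 and 0.1001). Quantile scaling ended these 3 (0.247, 0.442 and 0.463) and that of the respiratory chain (0.442), which then lay -0.004 from the median of all genes. Without the filter on low values none of the 5 was called (camera adjusted p = 0.116 to 0.463). A mean of at least 5 FPKM as the filter ended the calls of the respiratory chain (0.0565) and interferon response (0.0628), and a pseudocount of 5 that of the respiratory chain (0.161). Without Normal Ms1537 none of the 5 was called, without Normal Ms1535 only the mitochondrially encoded list was, and the calls of interferon response (camera adjusted p = 0.138), cardiomyocyte (0.0989) and erythroid genes (0.885) were lost without MI Ms1535. Without MI Ms1537 the cardiomyocyte call was lost (0.975), and without MI Ms1608 that of interferon response (0.2998). Without Normal Ms1608 all 5 stayed called (camera adjusted p from 1.79e-08 to 0.00450), but not with an estimated correlation (0.301 to 0.610). Medians there were -0.995 for cardiomyocyte, -0.10 for interferon response and -1.49 for erythroid genes. Myl2, a myosin light chain of heart muscle, had 158, 92.3 and 629 FPKM in MI Ms1535, Ms1537 and Ms1608 and 502, 312 and 5.53 FPKM in the Normal libraries. Hbb-bs, a beta globin with near-identical copies, had 311, 1214 and 5954 FPKM against 4936, 4851 and 685 FPKM. Rsad2, an antiviral interferon-induced enzyme, had 80.0 ± 70.7 FPKM against 74.7 ± 67.2 FPKM (SD, n = 3), and Cox6c, a subunit of cytochrome c oxidase, 1595 ± 214 FPKM against 1733 ± 726 FPKM (limma adjusted p = 0.720 and 0.991). The mitochondrial gene mt-Nd6 had 12454 and 6739 FPKM in MI Ms1535 and Ms1537, was listed at 0 in MI Ms1608, and had 32832, 32529 and 3187 FPKM in the Normal libraries. Other members went the other way, since mt-Cytb and mt-Nd1 had log2 differences of 4.93 (SE 3.86) and 4.84 (SE 3.51), with limma adjusted p of 0.512 and 0.480. Both were listed at 0 in MI Ms1608, Normal Ms1535 and Normal Ms1537, which may be failed estimates, so the call of this list rests on uncertain values.

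Other endothelial and signalling lists were not called by limma's camera with all 6 libraries. Venous (median 1.57, adjusted p = 0.135), endocardial (1.26, 0.101) and lymphatic endothelium (1.70, 0.0665) had medians above that of all genes, and arterial endothelium (0.46, 0.153), tip cell genes (0.72, 0.303) and fatty acid uptake and oxidation (0.62, 0.146) below it. Scaling moved some of these past the threshold: lymphatic endothelium was called higher after median-ratio, upper-quartile and quantile scaling (camera adjusted p = 0.0368, 0.0298 and 0.0385), endocardial after upper-quartile (0.0355) and venous after quantile scaling (0.0398). The remaining signalling and matrix lists had medians of 1.38 for basement membrane (adjusted p = 0.453), 0.92 for TGF-beta and BMP signalling (0.420), 0.74 for receptor tyrosine kinases (0.874), 0.43 for Notch (0.420) and 1.02 for Wnt signalling (0.459). Hypoxia response (0.92, adjusted p = 0.749), glycolysis (0.82, 0.793), cell cycle (1.30, 0.0561), inflammatory adhesion (1.14, 0.793), antigen presentation (0.83, 0.867) and immediate early and heat shock genes (0.95, 0.658) were not called either. Cell cycle genes were called higher after median-ratio (camera adjusted p = 0.0260) and upper-quartile scaling (0.0223), and immediate early and heat shock genes (0.00221) and B cell markers (0.00770) after quantile scaling. Neither were mural (0.19, adjusted p = 0.135), dendritic (0.82, 0.793), B cell (1.43, 0.443) and platelet markers (0.55, 0.459). Medians of arterial, Notch, mural, tip cell, fatty acid and receptor tyrosine kinase genes turned negative under at least 1 scaling. Adjusted over the list alone, 5 of 16 macrophage and monocyte, 3 of 6 lymphatic, 2 of 9 endocardial, 2 of 24 hypoxia, 2 of 7 dendritic and 1 of 12 receptor tyrosine kinase genes passed, all higher in MI. In 12 of the 35 lists, the median and the camera direction differed in sign, because camera compares with the other genes. Without Normal Ms1608, camera called arterial (median -0.37, adjusted p = 7.31e-08), tip cell (-0.20, 3.07e-05), fatty acid (0.40, 0.000107) and mural genes (-0.38, 2.44e-05) lower. Receptor tyrosine kinases (0.00688) and platelet markers (0.00219) were lower too. Antigen presentation (0.00868), immediate early (2.44e-05) and B cell genes (5.22e-07) were called higher. Each call was lost with an estimated correlation (adjusted p from 0.301 to 0.468). Among venous genes Mgp, matrix Gla protein, an inhibitor of calcification, was at 1489 ± 1632 FPKM in MI and 360.0 ± 301 FPKM in Normal over all 6 libraries (log2 difference 2.65, SE 1.33, limma adjusted p = 0.333). Normal Ms1608 held 13.4 FPKM of Mgp. Without that library the difference was 0.91, and it was -0.03 with median-ratio scaling added.

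At the level of single genes, limma called 1 gene higher and 0 lower in MI, and 1635 genes were higher and 21 lower at an unadjusted p under 0.05. These unadjusted counts moved with the shift of the median gene, to 546 and 95 after median-ratio, 467 and 128 after upper-quartile and 291 and 215 after quantile scaling. The called gene is Gm24890 (ENSMUSG00000077577.1), annotated as a small nuclear RNA of 102 nucleotides on the minus strand of chromosome 14, from 70428496 to 70428597 on GRCm38. It lies within the gene Piwil2, on the same strand, and overlaps none of its annotated exons. It had 277, 527 and 252 FPKM in MI Ms1535, Ms1537 and Ms1608 and was listed at 0 in all Normal libraries (limma adjusted p = 0.00156, with 0.000595 to 0.0362 over the settings that called few genes). Copies of small nuclear RNAs may share fragments, so its values are uncertain. In 2542 genes all MI values lay above all Normal values and in 36 below, together 25.4% of tested genes. After median-ratio, upper-quartile and quantile scaling these numbers were 1089 and 402, 931 and 525, and 567 and 689, or 14.7%, 14.3% and 12.4% of tested genes. With exchangeable libraries the average share would be 10%. Genes move together, so the share of a single split can lie far from that average. Other splits were not counted this way, so these shares are descriptive.

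The named genes of lowest unadjusted p after Gm24890 all missed the threshold, with a limma adjusted p = 0.245. Ear2, an eosinophil-associated ribonuclease with near-identical copies, had 27.8 ± 7.05 FPKM in MI and 0.799 ± 0.562 FPKM in Normal (SD, n = 3), a log2 difference of 4.03 (SE 0.67). Meg3, an imprinted long noncoding RNA, had 47.7 ± 32.9 FPKM against 1.43 ± 1.28 FPKM (4.14, SE 0.82). Clmp, an adhesion molecule, had 27.7 ± 20.7 FPKM against 0.865 ± 0.618 FPKM (3.72, SE 0.77), and Sema4b, a semaphorin, 10.8 ± 7.66 FPKM against 0.219 ± 0.0850 FPKM (3.09, SE 0.62). Top3a, Prr15 and Rab11fip1 had log2 differences of 1.65, 2.15 and 1.84. Izumo1r and Igkv10-94, an immunoglobulin segment, were listed at 0 in all Normal libraries, with 2.44 to 7.57 FPKM and 3.73 to 18.02 FPKM in MI. The basophil protease Mcpt8 was listed at 0 in Normal Ms1535 and Ms1537, with 0.0399 FPKM in Normal Ms1608 and 2.50 to 7.497 FPKM in MI. Among genes with lower values in MI, the 10 of lowest unadjusted p were Mtmr10, Hyls1, Kitl, Tyw3, Ctr9, Hmgb3, Dbf4, Itgb1bp2, Dcbld1 and Atp8b5, with limma adjusted p from 0.276 to 0.375. Kitl, the ligand of the receptor Kit, had 6.04 ± 4.003 FPKM in MI and 17.8 ± 5.12 FPKM in Normal, and Hyls1, a centriole protein, 1.74 ± 1.18 FPKM against 6.75 ± 2.22 FPKM. The values of Mtmr10, Kitl, Tyw3, Ctr9, Hmgb3, Dbf4, Dcbld1 and Atp8b5 were highest in Normal Ms1608.

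The counts changed when Normal Ms1608 was left out. With the remaining 5 libraries, limma called 452 genes higher and 7 lower, with a median shift of 0.83 log2 units, and 9 lists higher and 13 lower by camera, 0 of them with an estimated correlation. By fry 5 lists were called, all with medians above 0: antigen presentation (adjusted p = 0.000313), pan-leukocyte markers (0.00770), immediate early and heat shock genes and B cell markers (0.0188 for both) and glycolysis (0.0243). Fry compares with 0 and not with other genes, so the shift of the median gene enters these calls. Glycolysis stood 0.34 above the median of all genes and was not called by camera (adjusted p = 0.127), while the others were. Of the 18 pan-leukocyte markers, 16 passed the limma threshold over all genes in this comparison, and all 18 adjusted over the list alone (median 3.07, camera adjusted p = 6.45e-14, with 0.804 as the highest over settings, and adjusted p = 0.301 with an estimated correlation). Ptprc rose by 3.95 log2 units (SE 0.43, limma adjusted p = 0.0207, range over settings 0.00378 to 0.893) and Lat, an adaptor of T cell receptor signalling, by 3.98 (SE 0.61, adjusted p = 0.0210, range 0.00321 to 0.782). Also among the genes with the largest increases were Lilrb4, Ptpn22, Fgd2, Slpi, Ighm, Iglc2, Pilrb1 and Pilrb2, at 4.13 to 4.85 log2 units, of which the immunoglobulin and Pilrb genes have near-identical copies. T and NK cell markers (8 of 17), B cell markers (6 of 12), macrophage and monocyte markers (5 of 16) and immediate early and heat shock genes (10 of 31) had members higher past that threshold. All tested members of these lists had log2 differences above 0. Of 35 interstitial matrix genes 0 passed the limma threshold over all genes, while 27 had an unadjusted p under 0.05 and 26 passed adjusted over the list alone (camera adjusted p = 0.000111, and adjusted p = 0.610 with an estimated correlation). Rbp7, a retinol-binding protein of capillary endothelium, fell by 2.01 log2 units (SE 0.43, limma adjusted p = 0.0404, range 0.0348 to 0.997), with 95.1 ± 27.1 FPKM in MI against 435 and 324 FPKM in Normal Ms1535 and Ms1537, whereas its difference over all 6 libraries was 0.38 and turned negative under each scaling. The neurotrophin Ntf3, Wscd1 and Stox1 fell by 2.37, 2.196 and 2.12 log2 units, and the other 3 lower genes, Gm10722, 2610203C22Rik and Yam1, are a predicted gene and noncoding transcripts.

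**Figure D2:**
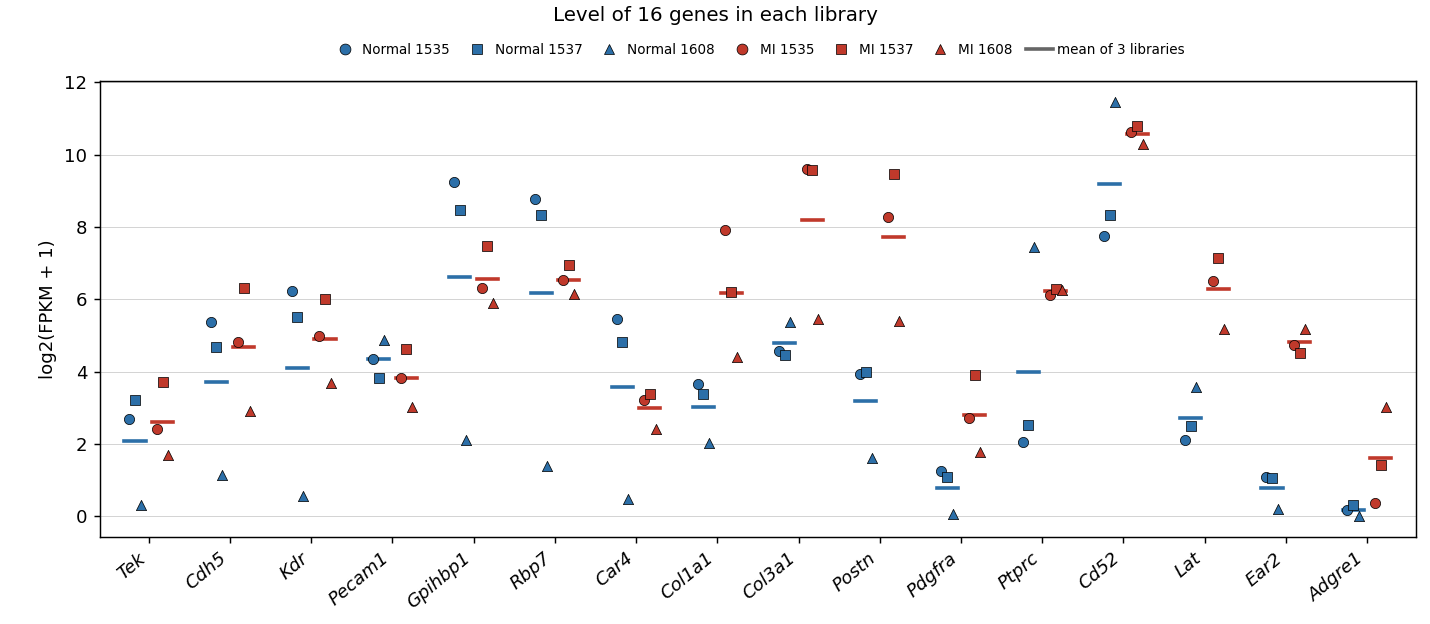
Values of 16 genes as log2(FPKM + 1) in each library, with Normal libraries in blue, MI libraries in red, symbols for the number in the sample title and bars for the mean of 3 libraries. Ptprc lay at 68.7 to 77.9 FPKM in MI and at 3.13, 4.72 and 174 FPKM in Normal Ms1535, Ms1537 and Ms1608, and differences of Tek, Cdh5, Kdr and Rbp7 turned negative under at least 1 scaling.

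Scaling limited what these calls show, since without Normal Ms1608 and with median-ratio scaling, limma called 2 genes higher (Gm24890 and Gm22107, another small nuclear RNA) and 0 lower, with 1158 and 674 at an unadjusted p under 0.05, and Ptprc at 3.11 log2 units had an adjusted p = 0.0751. Without both Ms1608 libraries, 1426 genes were called higher and 43 lower on the deposited scale, and 15 higher and 6 lower after median-ratio scaling, where the higher share was 71.4%. Of these 15 higher calls, mt-Rnr2, mt-Cytb, mt-Nd1, the pseudogenes Gm29216, Gm28661 and Gm28437 and the small RNA Gm22579 were listed at 0 in Normal Ms1535, Normal Ms1537 and MI Ms1608, so the share rests in part on possible failed estimates. The others were the small RNAs Gm24890 and Gm22107, the noncoding transcript Gm29243, and Col3a1, Postn, Timp1, Cxcl3 and Angptl7. Of the 35 interstitial matrix genes, 25 passed the limma threshold over all genes without both Ms1608 libraries on the deposited scale and 33 adjusted over the list alone, or 3 and 22 after median-ratio scaling, and the camera call was again lost with an estimated correlation (adjusted p = 0.362 on the deposited scale). The 6 genes called lower after scaling were Rbp7, Myl3, Pxmp2, mt-Rnr1, mt-Nd3 and the pseudogene Gm10222. Between the Ms1608 libraries, which had not entered this choice of genes, 39 of the 43 genes called lower on the deposited scale were higher in MI. Of the 1426 genes called higher there, 737 were lower in MI, or 613 with median-ratio scaling. The median tested gene was 0.52 log2 units higher in MI between the Ms1608 libraries, and the share over all tested genes was not counted.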

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

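The settings that leave out both Ms1608 libraries, or Normal Ms1608 together with scaling or a block, were chosen after seeing the data. The count of genes higher in MI was 1 and of genes lower 0 under all other pseudocounts, filters, scalings, limma settings and thresholds. Library weights, which gave Normal Ms1608 a weight of 0.117, moved the counts to 3209 higher and 79 lower. Leaving out each library in turn gave 1 to 452 genes higher and 0 to 7 lower, with the highest of both without Normal Ms1608, and 1 lower, a pseudogene, without MI Ms1537. Without Normal Ms1608 and with median-ratio scaling, 2 genes were higher and 0 lower, and without both Ms1608 libraries 1426 and 43, or 15 and 6 with that scaling. Fewer libraries and the removal of an outlying library enter these counts together. Without Normal Ms1608 the groups also differ in sex-linked genes. MI Ms1608 held 23.0 FPKM of the Y-linked gene Ddx3y, and the other libraries kept held at most 0.0521 FPKM. The cause of the changed counts was not tested.

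The 12 lists called became 24 with library weights, 3 to 22 with each library left out (4 without Normal Ms1535, 3 without Normal Ms1537, 22 without Normal Ms1608), 22 without Normal Ms1608 with scaling, 24 without both Ms1608 libraries and 21 with scaling. With all 6 libraries, 0 lists were called with an estimated correlation or with fry, and 9 to 16 under the remaining settings. A minimum fold could not be applied to a list test. Interstitial matrix and mesenchymal transition were called higher in 23 of 23 settings with the preset correlation and fibroblast markers in 22.

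Over the 115 named genes tested, settings without a Ms1608 library took 216 values past the threshold in the same direction and 4 in the opposite direction. They left 470 on the same side of it. In other settings these numbers were 83, 2 and 1969, and only library weights called named genes there, 85 of them. Part of the named genes were taken because they passed the threshold without a Ms1608 library, so the 216 is in part built in. Over all 10168 tested genes, 452 were called higher and 7 lower without Normal Ms1608. The sign differed in 59 of 690 values without a Ms1608 library and in 62 of 2054 elsewhere, mostly among values that missed the threshold. The log2 fold change of Rbp7, at 0.38, ranged from -2.01 (without Normal Ms1608) to 1.68 with each library left out. It was -1.80 with library weights, -1.81 without both Ms1608 libraries and -2.94 with scaling added. The log2 fold change of Myl2, at 1.06, was -1.71 without both Ms1608 libraries, and the log2 fold change of Gng11, at 0.47, was -1.64 with library weights. The cause was not tested.

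With the replicate number as a block, 1 gene was higher, 0 lower and 15 lists were called, and without Normal Ms1608 the block gave 667 higher, 19 lower and 23 lists. Deviations of same-numbered libraries correlated at -0.05, 0.10 and 0.09 for Ms1535, Ms1537 and Ms1608, and not every library correlated best with its own number, so pairing was not established. Same-numbered libraries were alike in the sex-linked genes Xist and Ddx3y. These genes do not tell Ms1535 from Ms1537, and they cannot show that the same mouse gave both libraries.

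The splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split gave 1 gene and the highest other 9, with 6 of 10 splits giving as many, and for lists the real split gave 12 and the highest other 23, with 7 of 10 giving as many. The split of Normal Ms1608 with MI Ms1535 and Ms1537 from the rest, which exchanged Ms1608 labels would make the real one, gave the 9 genes. These exceed the real count, so a structure of the libraries besides MI and Normal stays possible. At an unadjusted limma p under 0.05 the real split gave the most genes of the 10 on the deposited scale, 1656 against 1297 for the split with 9 genes. The real count fell to 641, 595 and 506 after median-ratio, upper-quartile and quantile scaling, and the other splits were not repeated on scaled values. At these depths 3 fragments on a gene of 2 kb equal 0.0324 to 0.0453 FPKM, and values near that are not distinguishable from 0.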

Other observations

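All tests of explanations in this part were chosen only after the results they bear on had been seen. MI Ms1535 held cell type transcripts that the other MI libraries had at low levels. The mast cell proteases Cma1, Cpa3 and Mcpt4 had 521, 333 and 69.6 FPKM in MI Ms1535, at most 5.44, 2.88 and 0.0353 FPKM in MI Ms1537 and Ms1608, and 88.4, 73.2 and 7.42 FPKM in Normal Ms1608. The mesothelial genes Wt1 and Clu had 83.6 and 66.1 FPKM in MI Ms1535, against at most 13.0 and 25.3 FPKM elsewhere, and Msln, mesothelin, had 4.84 FPKM against at most 0.317 FPKM. Of the 11 mesothelial genes, 7 were highest in MI Ms1535. Others were not, with Krt19 and Gpm6a at 32.4 and 31.1 FPKM in Normal Ms1608 and 0.0148 and 7.51 FPKM in MI Ms1535, and Krt18 at 2.53 FPKM in MI Ms1537 and 0.406 FPKM in MI Ms1535. The immunoglobulin genes Iglc1, Igha and Igkc, which share near-identical sequences, had 15295, 11646 and 2364 FPKM in MI Ms1535 and at most 234, 585 and 356 FPKM in the other libraries. Mast cell, Schwann cell and mesothelial lists held too few tested genes for a list test.

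Individual matrix and fibroblast genes varied between MI libraries. Cthrc1, a marker of activated fibroblasts, had 43.7 and 21.6 FPKM in MI Ms1535 and Ms1537, 0.0391 FPKM in MI Ms1608 and at most 0.147 FPKM in Normal. Comp, a cartilage matrix protein, had 20.8, 136 and 1.60 FPKM in MI and at most 1.21 FPKM in Normal, and Lox, which crosslinks collagen, had 14.7, 33.0 and 0.255 FPKM against at most 0.831 FPKM. The Wnt inhibitor Wif1 went the other way, with 7.91 and 2.28 FPKM in Normal Ms1535 and Ms1537 and at most 0.1296 FPKM in the other 4 libraries. Pi16, Gsn and Meox1, other fibroblast markers, had 17.95, 122 and 4.57 FPKM in MI Ms1535, 117, 709 and 19.8 FPKM in MI Ms1537 and 85.4, 212 and 7.47 FPKM in MI Ms1608. They had 48.8, 212 and 10.7 FPKM in Normal Ms1535, 16.6, 186 and 10.5 FPKM in Normal Ms1537 and 1.22, 8.35 and 0.260 FPKM in Normal Ms1608. Xist, expressed in female cells, had 7.14, 13.9, 2.38 and 1.60 FPKM in MI Ms1535, MI Ms1537, Normal Ms1535 and Normal Ms1537 and at most 0.133 FPKM in both Ms1608 libraries. The Y-linked gene Ddx3y had 23.0 and 5.53 FPKM in MI Ms1608 and Normal Ms1608 and at most 0.0521 FPKM elsewhere, so the Ms1608 libraries also differ from the others in these sex-linked genes. The microRNA gene Mir3099 was listed at 43800000 FPKM in MI Ms1608 and at 0 in the other libraries.

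Normal Ms1608 had little endothelial RNA and much leukocyte RNA, with 29.0 FPKM of Fabp4 against 3049 and 5003 in the other Normal libraries, and 6890.1 FPKM of S100a8 against 1069.9 and 1200.3. The implied totals gave no sign of lower depth, since its total was 0.912 of the median of the other libraries. An exchange of labels with MI Ms1608 stays open: among genes called without either Ms1608 library, 39 of 43 lower and 51.7% of 1426 higher genes differed the opposite way between the Ms1608 libraries (Fn1 with 122.7 FPKM in Normal Ms1608 and 19.6 in MI Ms1608, Timp1 with 100.4 and 8.27). Spp1, not among these calls, had 31.2 and 1.12 FPKM there, and the cardiomyocyte median was 5.41 in MI Ms1608, 4.76 and 4.05 in Normal Ms1535 and Ms1537 and 3.42 and 1.72 in the other MI libraries, whereas 29 of 35 interstitial matrix genes were higher in MI Ms1608 and its pan-leukocyte median was 5.89 against at most 2.88 in Normal Ms1535 and Ms1537. The median tested gene was 0.52 log2 units higher in MI Ms1608 than in Normal Ms1608, whose cardiomyocyte median was 0.59. Part of the 39 genes may follow from that without an exchange. The share over all tested genes was not counted, so these counts cannot decide on an exchange. A candidate explanation is that the sorted cells were mostly leukocytes, which the Tie2-Cre lineage includes and the F4/80 gate does not remove apart from macrophages. The fibroblast, cardiomyocyte and mural medians lay below both other Normal libraries in 3 of 3 lists. Normal Ms1608 also had fewer genes at 1 FPKM or more, 6882 against 8930 and 8474 in the other Normal libraries. Low medians could follow from that under other explanations too, so this test cannot decide. Of the 18 pan-leukocyte markers, 16 were also at 1 FPKM or more in both other Normal libraries and 0 stand in another list. Neither explanation excludes the other. The sex-linked genes Xist and Ddx3y set both Ms1608 libraries apart from the others, so the source animals differed in these genes. MI Ms1608 shares that difference, so it does not by itself explain Normal Ms1608. Whether the mouse, the tissue, the label or the sort accounts for the make-up of Normal Ms1608 stays open.

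The interstitial matrix list was called higher in MI at a preset correlation, while the call was lost with an estimated correlation (adjusted p = 0.816), and by limma 0 of its 35 members passed the threshold with 6 libraries, 25 without both Ms1608 libraries and 3 when these were also scaled. A scale factor common to all genes of a library was not the whole cause, since the median difference was 1.72 after median-ratio scaling without the Ms1608 libraries. In these libraries the list stood 1.68 above the median of all genes before that scaling and 1.60 after it. The scaled value thus repeats an offset already seen and is no independent check. More fibroblasts of the same make-up as in normal tissue cannot be told apart from a change within them: the matrix median minus the median of the 8 fibroblast markers outside that list was 1.93, 1.65 and 0.49 in MI Ms1535, Ms1537 and Ms1608 and -0.45, -0.41 and 0.57 in the Normal libraries, a mean difference of 1.45 (exact permutation test, two-sided p = 0.2, where 3 against 3 cannot go below 0.1). Fibroblasts in another state, or matrix expression by endothelial cells after MI, may each account for the pattern as well, and these bulk values did not test them. The gate on tdTomato should remove fibroblasts outside the Tie2-Cre lineage. Heart muscle RNA was present despite the gate, with Myl2 at 502 and 312 FPKM in Normal Ms1535 and Ms1537. Fibroblast RNA as the source thus need not mean that fibroblasts passed the gate, which was not tested.

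The median gene was 0.78 log2 units higher in MI. The implied totals gave no sign of lower depth in Normal, since the mean of the Normal libraries was 0.930 of that of MI. Mitochondrial transcripts may take a larger part of the FPKM denominator in some libraries: mt-Nd2 and the sum of nuclear coding FPKM times length had a Spearman rho of -0.83 (exact permutation p = 0.0583) and a Pearson r of -0.87 (exact permutation p = 0.0556) over 6 libraries, and r was -0.98 without the 2 farthest, MI Ms1608 and Normal Ms1537. This was the only relation tested, so adjustment leaves p as it is. Both values share that denominator, so a negative relation is in part built in, and p missed 0.05. The Ms1608 libraries went against it, with mt-Nd2 at 24104 FPKM in MI and 1476 in Normal, while the median gene was 0.52 log2 units higher in MI. Normal libraries also had fewer genes at 1 FPKM or more (8930, 8474 and 6882 against 11450, 11294 and 10317), and the part of this was not tested. With 6 libraries, these and a biological rise cannot be told apart.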
